A study of Homo sapiens with 6 samples.

How the data were processed

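The data are mRNA levels of human epidermal keratinocyte progenitors of the stratum basale, grown in CnT-PCT medium. Every culture was held for 24 h with IL-17A (100 ng/ml), IL-22 (100 ng/ml) and TNFα (10 ng/ml), a psoriasis-like cytokine mixture, and then treated for 24 h. The control solvent held 3% dimethyl isosorbide, 40% glycerin and 57% butylene glycol. It was given alone, with bakusylan at 10 µg/ml or with all-trans-retinoic acid (ATRA) at 0.1 µg/ml. Bakusylan is the salicylic acid ester of bakuchiol, per the title of the series. Each of the 3 groups has 2 arrays, 6 in all, each hybridised with biotin-labelled cRNA made from 6 µg of total RNA. The labels do not say whether the replicates are separate cultures, so the p-values of single genes measure only the spread between these samples, which may be technical. Those of gene lists are described below. No group without cytokines is part of the series.

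The deposited values are log2 probe-set intensities made by the authors with RMA (robust multi-array average). Per the labels, the software version is not given. The values were used as deposited, without a further logarithm. The table holds 54675 probe sets on a human whole-genome Affymetrix array, with a median between 4.41 and 4.43 on each array. No intensities of single probes were used here. For arrays, the number of samples limits the precision: 2 per group.

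Probe sets were given gene names from a probe table, which lists 42898 of them. The 41097 probe sets with exactly 1 symbol (75.2%) stand for 19775 genes. The 1801 with several symbols, the 62 Affymetrix control probe sets and 11721 that the probe table does not list were left out of the gene tests. Entrez identifiers were checked against the RefSeq gene list of GRCh38.p14, used for names alone, which changed 0 symbols. Each gene was represented by its probe set with the highest mean over the 6 arrays. The 25% of genes with the lowest mean (4944 genes, below a log2 value of 3.68) were left out, which left 14831 genes. Other probe sets of a named gene are reported, and counted for their sign, only where their mean lay above that value.

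The 3 comparisons (bakusylan against control solvent, ATRA against control solvent, bakusylan against ATRA) came from 1 group-means model in limma 3.58.1 under R 4.3.3. The model pooled the spread over all 6 arrays, with 3 residual degrees of freedom and 3.14 from the empirical Bayes prior. Tests were two-sided limma moderated tests. P-values were adjusted by Benjamini-Hochberg over all genes tested in a comparison, with a threshold of 0.05. The adjusted p-values below, where no other test is named, are from limma. Standard errors (SE) and 95% confidence intervals come from the same model, n = 2 arrays per group throughout. Rose and fell are used of genes past that threshold.

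Before the data were examined, the groups, the tests, the 30 gene lists, the rule for the genes named and all alternatives were written down. A list was tested with limma's camera, which compares its genes with the other genes tested. It was run at a preset correlation between genes of 0.01 and, as an alternative, with an estimated correlation. The preset test measures a list against the spread across genes, taken as nearly independent. Its small p-values therefore do not rest on the spread between arrays alone. The alternative takes its p-value from the 3 residual degrees of freedom, so a list has to shift far to pass it. Estimates were 0.125 for the interferon list, 0.088 for the sterol list and 0.009 for the NRF2 list. P-values of camera were adjusted over the 30 lists of a comparison. Gene counts are also given adjusted over the list alone. The core lists are retinoid response, cytokine and chemokine genes, antimicrobial and alarmin genes, and cornified envelope and late differentiation. The others are the IL-17, IL-22 and TNF response, genes raised in psoriasis lesions, keratins of activated keratinocytes, basal keratinocyte and basement membrane genes, cell cycle and mitosis, and the interferon response. To these come sterol synthesis and LDL uptake, the LXR and PPAR response, epidermal lipid and ceramide synthesis, the NRF2 response, the AHR response, the endoplasmic reticulum stress and amino acid response, heat shock, and metallothioneins. Further lists hold the p53 response, hypoxia and glycolysis, matrix and proteases, EGFR ligands and immediate early genes, hyaluronan, aquaporin and tight junction genes, and prostaglandin metabolism. The last are the mitochondrial respiratory chain, ribosomal proteins, and markers of melanocytes, Langerhans and other immune cells, fibroblasts and endothelial cells.

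The rule names, for each compound against the control solvent, the 10 genes with the largest change in each direction among those past the threshold, and 5 in each direction for bakusylan against ATRA. It adds up to 4 changed members of each list that passed camera and of the core lists, filled up to 2 with the smallest p where fewer passed, and up to 2 changed members of the other lists. XIST and Y-linked genes, uncharacterised loci and antisense transcripts were not named. A few genes outside the rule are marked in the text as chosen after their values were seen.

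The response common to both compounds was measured as the covariance of their log2 fold changes across genes and as the overlap of changed genes. Because both comparisons share the control arrays, 100 simulated data sets without any treatment effect gave the covariance and correlation that sharing alone produces. They say nothing about the overlap, since almost no gene passes the threshold in such data. The alternatives tried were no filter on dim genes or a 50% filter, the mean of all probe sets or every probe set alone, a second quantile normalization, centring each array on its median, a variance prior with an intensity trend, with and without a robust prior, and array weights. Also tried were the replicate number as a block, only the 4 arrays of the groups compared, other thresholds, separate control arrays for each compound, and leaving out each array in turn. The pipeline was tested on 20 simulated data sets of 14831 genes. In these, a true 2-fold change was called in 90.7% of genes for bakusylan, 91.4% for ATRA and 93.8% for the direct comparison. A true 1.5-fold change was called in 62.7%, 65.2% and 73.6%.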

Results

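The data set holds 6 arrays of human epidermal keratinocyte progenitors kept in a psoriasis-like cytokine mixture: 2 with control solvent, 2 with bakusylan and 2 with ATRA, a retinoid. Array medians lay between 4.41 and 4.43 (log2 RMA). Pearson correlations over the 14831 genes tested were 0.998 between the control arrays, 0.997 between the bakusylan arrays and 0.998 between the ATRA arrays. Between groups they ran from 0.994 to 0.996, measured across genes, which are not independent replicates. The difference between the 3' and 5' control probe sets of GAPDH, a measure of RNA integrity, was 0.21 and 0.33 (log2) on the control arrays, and 0.15 to 0.20 on the treated arrays. For ACTB it was 0.64 and 0.73 on the control arrays, and 0.55 to 0.59 on the treated arrays. On both measures both control arrays lay above every treated array. In each comparison with the control solvent, RNA integrity and treatment thus go together, and their effects were not separated. Probe sets for 18S rRNA averaged 11.27 and 9.18 on the control arrays, 10.51 and 11.75 with bakusylan, and 10.43 and 11.22 with ATRA.

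The comparison of bakusylan with the control solvent asks what the ester changes in cytokine-treated keratinocytes. DTL, a substrate receptor of a ubiquitin ligase that acts in S phase, rose 5.08-fold (log2 change 2.34, SE 0.14, n = 2 per group, adjusted p = 0.00657). CCNE2, a cyclin of S phase entry, rose 3.36-fold (1.75, SE 0.06, adjusted p = 0.00105). INSIG1, a regulator of sterol synthesis, fell (-1.48, SE 0.07, adjusted p = 0.00385), as did HMGCS1, an enzyme of the mevalonate pathway (-1.20, SE 0.06, adjusted p = 0.00392). The interferon-induced genes IFIT1 (-1.94, SE 0.29, adjusted p = 0.0408) and MX2 (-1.59, SE 0.10, adjusted p = 0.00657) fell too. In all, 221 of 14831 genes changed, 156 of them higher (70.6%) and 65 lower.

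Among the genes with the largest rises were HPGD, the enzyme that inactivates prostaglandins (log2 change 1.96, SE 0.13), and the replication factors MCM10 (1.62, SE 0.20), CDC6 (1.47, SE 0.08) and PRIM1, a DNA primase subunit (1.27, SE 0.11). TRIM63, a ubiquitin ligase known from muscle, rose by 1.40 (SE 0.10), and SCNN1G, a subunit of the epithelial sodium channel, by 1.24 (SE 0.18). CEMIP, which takes part in hyaluronan breakdown, rose by 1.34 (SE 0.15), while its other probe set gave -0.08. The largest falls included IFIT3 (-1.48, SE 0.16), IFI44L (-1.41, SE 0.17) and OAS2 (-0.98, SE 0.07), all interferon-induced. FASN, the fatty acid synthase, fell by 1.23 (SE 0.12), with -0.12 from its other probe set and -0.68 with the mean of its probe sets. ACSS2, which makes acetyl-CoA from acetate, fell by 1.01 (SE 0.09). MYOCD, a muscle transcription coactivator, fell by 1.13 (SE 0.09) at a mean of 3.79 on the bakusylan arrays, close to the 3.68 below which genes were left out. The adjusted p-values of these genes lay at or under 0.0398.

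Of the 25 genes of sterol synthesis and LDL uptake, 15 fell, 21 adjusted over the list alone, and the other 10 did not pass. INSIG1, HMGCS1 and FASN were joined by IDI1, an isomerase of isoprenoid synthesis (-0.86, SE 0.07, adjusted p = 0.0112; a further probe set gave 0.09). The median change of the list was -0.45 (camera adjusted p = 6.32e-21, and adjusted p = 0.129 with an estimated correlation). Of the 45 interferon response genes, 12 fell, 27 adjusted over the list alone, and 33 did not pass. Their median was -0.38 (camera adjusted p = 2.38e-19, and adjusted p = 0.220 with an estimated correlation). Beside these values, the GAPDH 3' to 5' difference was 0.21 and 0.33 on the control arrays and 0.20 and 0.15 on the bakusylan arrays.

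Of the 63 genes of cell cycle and mitosis, 14 rose, 1 fell and 48 did not pass. The counts were 30 and 7 adjusted over the list alone. CCNE2, MCM10 and CDC6 were joined by RRM2, a subunit of ribonucleotide reductase (1.22, SE 0.16, adjusted p = 0.0350). The gene that fell was KIF20A, a mitotic kinesin (-0.88, SE 0.12, adjusted p = 0.0373), named after its values were seen. The list median was 0.29 (camera adjusted p = 7.69e-06, and adjusted p = 0.498 with an estimated correlation). Without control replicate 2 the median was 0.15 and the list no longer passed (adjusted p = 0.0924, within a range of 2.82e-12 to 0.498 over its alternatives).

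Of the 42 genes of the cornified envelope and late differentiation, 0 passed in limma, over all genes or adjusted over the list alone, and 17 were higher at an unadjusted p under 0.05. The median was 0.29, with 37 genes at positive values (camera adjusted p = 1.35e-07, and adjusted p = 0.498 with an estimated correlation), and it was 0.15 without bakusylan replicate 1. The desmosomal cadherin DSC2 was at 0.31 (SE 0.07, adjusted p = 0.111), and the protease KLK12 at 0.34 (SE 0.07, adjusted p = 0.0925). Of the 21 hyaluronan, aquaporin and tight junction genes, 4 rose, 9 adjusted over the list alone, with a median of 0.22 (camera adjusted p = 6.66e-05, and adjusted p = 0.297 with an estimated correlation), and the median was 0.13 without the dim-gene filter. Besides CEMIP these were AQP3, a water and glycerol channel (0.83, SE 0.11, adjusted p = 0.0371), and the tight junction genes CGN (0.76, SE 0.07, adjusted p = 0.0169) and CLDN1 (0.62, SE 0.10, adjusted p = 0.0436). Of the 26 genes of epidermal lipid and ceramide synthesis, 2 rose: SDR9C7 (1.26, SE 0.15, adjusted p = 0.0261) and FA2H, a fatty acid hydroxylase (0.77, SE 0.09, adjusted p = 0.0265; another probe set gave -0.20). In that list 6 rose and 1 fell adjusted over the list alone, with a median of 0.18 (camera adjusted p = 4.2e-04, and adjusted p = 0.498 with an estimated correlation).

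Of the 31 genes of the NRF2 and oxidative stress response, 7 rose, 19 adjusted over the list alone, with a median of 0.32 (camera adjusted p = 1.46e-11, and adjusted p = 0.129 with an estimated correlation). They included PIR (1.09, SE 0.08), the glutathione peroxidase GPX2 (0.90, SE 0.12), heme oxygenase HMOX1 (0.72, SE 0.10) and the quinone reductase NQO1 (0.68, SE 0.06), with adjusted p-values from 0.00900 to 0.0358. Of the 39 genes of the endoplasmic reticulum stress and amino acid response, 6 rose, 14 adjusted over the list alone, with a median of 0.12 (camera adjusted p = 2.99e-06, and adjusted p = 0.498 with an estimated correlation). Examples were SDF2L1 (0.67, SE 0.08), CRELD2 (0.66, SE 0.07) and PDIA4 (0.54, SE 0.06), all proteins of the endoplasmic reticulum, and the cystine transporter SLC7A11 (0.58, SE 0.08), with adjusted p-values from 0.0196 to 0.0393.

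Of the 20 genes of prostaglandin metabolism, 2 rose, HPGD and the prostaglandin E synthase PTGES (0.51, SE 0.08, adjusted p = 0.0428), and 3 rose adjusted over the list alone. The median was 0.12 (camera adjusted p = 0.00289, and adjusted p = 0.498 with an estimated correlation), and the list no longer passed without bakusylan replicate 1 (adjusted p = 0.204, within 3.85e-05 to 0.498 over its alternatives). The median was 0.21 without bakusylan replicate 2. Of the 18 antimicrobial and alarmin genes, 0 passed in limma, also adjusted over the list alone, and 4 were higher at an unadjusted p under 0.05. DEFB1, a beta-defensin, was at 0.68 (SE 0.19, adjusted p = 0.149), and PGLYRP2 at 0.35 (SE 0.10, adjusted p = 0.152). The list median was 0.14 (camera adjusted p = 0.0240, and adjusted p = 0.560 with an estimated correlation). This list no longer passed without the dim-gene filter (adjusted p = 0.0794), without control replicate 1 (adjusted p = 0.259) or without bakusylan replicate 1 (adjusted p = 0.231), within 0.00222 to 0.560 over its alternatives. Its median was 0.05 without control replicate 1, 0.27 without control replicate 2, 0.06 without bakusylan replicate 1 and 0.31 without bakusylan replicate 2.

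The remaining lists did not pass camera with bakusylan. Of the 29 retinoid response genes, 1 rose, AQP3, and 2 adjusted over the list alone, with a median of 0.09 (camera adjusted p = 0.0517). DHRS9, a retinol dehydrogenase, was at 0.82 (SE 0.16, adjusted p = 0.0751). Of the 38 cytokine and chemokine genes, IL36B rose (0.53, SE 0.07, adjusted p = 0.0371), CSF3 fell (-0.45, SE 0.07, adjusted p = 0.0428) and 36 did not pass, against 2 that rose and 4 that fell adjusted over the list alone. The median of this list was 0.008, while its mean was -0.03 and its test was on the lower side (camera adjusted p = 0.644). Of the 36 genes of the IL-17, IL-22 and TNF response, SOCS1, an inhibitor of cytokine signalling, rose (0.50, SE 0.08, adjusted p = 0.0466), with a list median of 0.04 (camera adjusted p = 0.936). Of the 37 genes raised in psoriasis lesions, 1 fell, OAS2, and the median was 0.16 (camera adjusted p = 0.0661). Adjusted over the list alone, 2 rose and 2 fell in the cytokine response list, and 3 rose and 5 fell in the psoriasis list.

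Among further lists, PLIN2, a lipid droplet protein (0.71, SE 0.07), and CPT1A, which brings fatty acids into mitochondria (0.45, SE 0.07), rose in the LXR and PPAR response (median 0.07, camera adjusted p = 0.152). OVOL1 (0.88, SE 0.12) and NQO1 rose in the AHR response (0.03, 0.364), and EGR3, an immediate early gene (0.96, SE 0.06), among EGFR ligands and immediate early genes (median -0.04, camera adjusted p = 0.0740). PLAUR, the urokinase receptor, rose (0.69, SE 0.07) and PLAT, the tissue plasminogen activator, fell (-0.57, SE 0.07) among 37 genes of matrix and proteases (median 0.007, camera adjusted p = 0.567). The zinc exporter SLC30A1 rose (0.48, SE 0.06) in the metallothionein list, whose median was -0.07 and mean 0.003 (test on the lower side, camera adjusted p = 0.561). PFKFB4 fell (-0.54, SE 0.08; its other probe set gave 0.03) among 36 genes of hypoxia and glycolysis (median 0.03, camera adjusted p = 0.644). The adjusted p-values of these genes lay between 0.00697 and 0.0469. Adjusted over the list alone, 7 rose and 2 fell in the LXR and PPAR response, 2 rose in the AHR response, 2 rose and 6 fell among immediate early genes, 5 rose and 2 fell among matrix genes, 1 rose among metallothioneins, and 1 rose and 2 fell in hypoxia and glycolysis.

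In the remaining lists 0 genes passed in limma with bakusylan over all genes tested. Adjusted over the list alone, 3 heat shock genes, 1 basal keratinocyte gene and 1 melanocyte marker rose, and 1 melanocyte marker fell. Basal keratinocyte genes had a median of -0.10 (camera adjusted p = 0.0517, 3 higher and 4 lower at an unadjusted p under 0.05), keratins of activated keratinocytes 0.12 (0.427, 1 higher and 1 lower), heat shock genes 0.04 (0.179, 3 higher) and p53 response genes 0.02, with the test on the lower side (0.958, 2 higher and 1 lower). Respiratory chain genes had a median of 0.01 (camera adjusted p = 0.731) and ribosomal protein genes 0.003, with the test on the lower side (0.749), each with 0 genes at an unadjusted p under 0.05. Markers of other cell types were at medians of 0.22 for endothelial cells (camera adjusted p = 0.116, 2 higher at an unadjusted p under 0.05), 0.08 for fibroblasts (0.173, 1 higher), -0.03 for immune cells (0.489, 0 at that level) and -0.004 for melanocytes, with the mean at 0.04 and the test on the higher side (0.932, 2 higher and 1 lower).

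The 51 genes named for bakusylan were chosen by their values on these arrays, and for each of them both bakusylan arrays lay on the same side of both control arrays. With the mean of all probe sets of a gene, 10 of them no longer passed: CEMIP (0.63), SCNN1G (0.59), IL36B (0.33), SOCS1 (0.24), CPT1A (0.26), FA2H (0.28), GPX2 (0.44), PFKFB4 (-0.26), SLC30A1 and PTGES. MCM10 (0.94), OAS2 (-0.57), IDI1 (-0.39) and PLIN2 (0.40) passed with that mean at smaller values than those above. Of the 14831 genes, 2485 had an unadjusted p under 0.05 and 30 changed at least 2-fold. The count of 221 ranged from 61 to 903 over 13 other settings with all arrays or the 4 arrays compared. It was 12 without control replicate 1, 8 without control replicate 2, 28 without bakusylan replicate 1, 6 (3 higher and 3 lower) without bakusylan replicate 2 and 61 without either ATRA array. CCNE2, HMGCS1 and INSIG1 stayed past the threshold under every alternative run, and other genes named above did not.

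**Figure D1:**
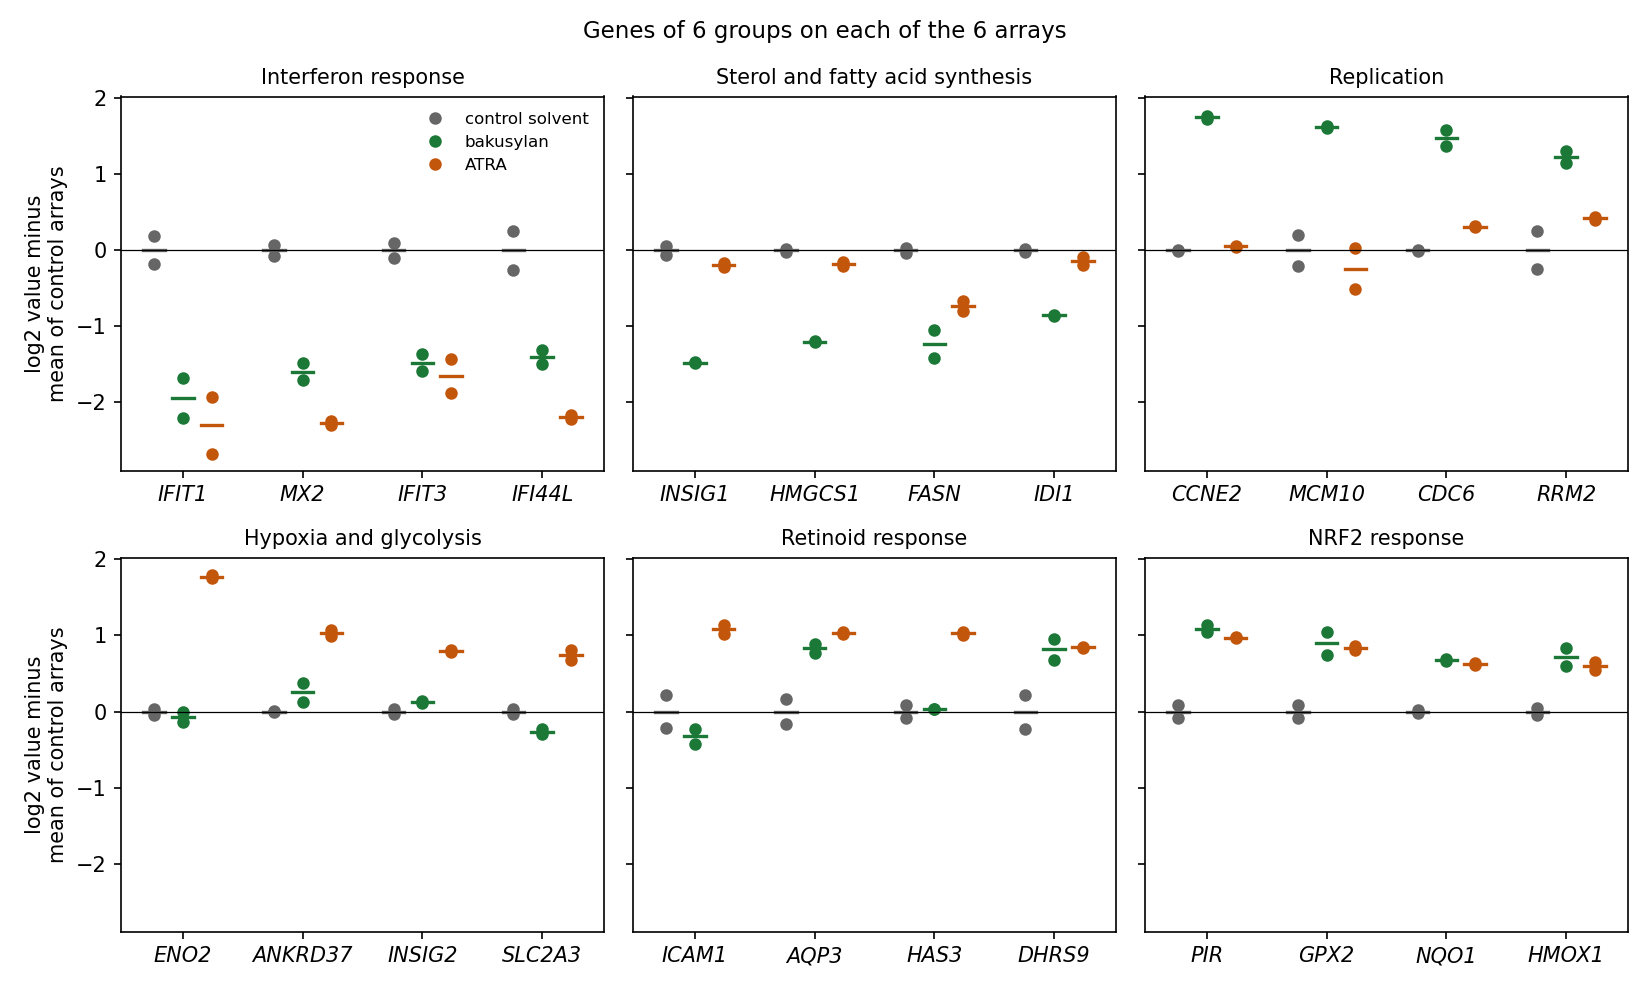
Log2 expression of 24 genes on each array, as the difference from the mean of the 2 control arrays, in 6 panels by gene group; each dot is 1 array and each bar the mean of its 2 arrays. IFIT1 and MX2 lie below the controls with both compounds, INSIG1 and HMGCS1 fell with bakusylan by 1.48 and 1.20, and ENO2 rose by 1.77 with ATRA.

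The comparison of ATRA with the control solvent shows what the retinoid changes in the same cells. HPGD rose 7.55-fold (log2 change 2.92, SE 0.13, n = 2 per group, adjusted p = 0.00129), and ANGPTL4, a secreted inhibitor of lipoprotein lipase, 3.63-fold (1.86, SE 0.08, adjusted p = 0.00129). ENO2, a glycolytic enolase, rose by 1.77 (SE 0.07, adjusted p = 0.00129). The interferon-induced genes IFIT1 (-2.30, SE 0.29, adjusted p = 0.0151) and MX2 (-2.27, SE 0.10, adjusted p = 0.00129) fell. In all, 735 genes changed, 406 of them higher (55.2%) and 329 lower, a split that turned to 649 higher and 677 lower with the dimmest 50% of genes left out.

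Further large rises were those of GALNT12, a glycosyltransferase of mucin-type O-glycans (2.74, SE 0.35), IGFBP3, a binding protein of insulin-like growth factors (2.39, SE 0.40), THBD, thrombomodulin (2.31, SE 0.33), and GPRC5A, a retinoic acid-induced receptor (1.89, SE 0.23). STC1, a secreted glycoprotein, rose by 1.87 (SE 0.15), S100P, a calcium-binding protein, by 1.74 (SE 0.23), and TENT5A by 1.73 (SE 0.11; its other probe sets gave 0 to 1.63), with adjusted p-values of these genes at or under 0.0311. The largest falls included CYP24A1, the vitamin D hydroxylase (-2.07, SE 0.19), DKK1, a Wnt antagonist (-1.98, SE 0.21), the cytokine IL24 (-1.90, SE 0.17), the collagen COL8A1 (-1.71, SE 0.25) and DNER, a Notch ligand (-1.65, SE 0.14). IFI44L (-2.19, SE 0.17), IFIT3 (-1.65, SE 0.16) and OAS2 (-1.51, SE 0.07) fell as well, with adjusted p-values of these genes at or under 0.0206.

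Of the 45 interferon response genes, 25 fell and 20 did not pass. In the test adjusted over the list alone, 33 fell and 2 rose. The median was -0.63 (camera adjusted p = 2.87e-19, and adjusted p = 0.269 with an estimated correlation). Beside these values, the GAPDH 3' to 5' difference was 0.21 and 0.33 on the control arrays and 0.16 on each ATRA array. Of the 36 genes of hypoxia and glycolysis, 14 rose, 17 adjusted over the list alone, and 35 were at positive values, with a median of 0.18 (camera adjusted p = 5.17e-13, and adjusted p = 0.348 with an estimated correlation). Besides ENO2 these included ANKRD37 (1.03, SE 0.09), INSIG2, a regulator of sterol synthesis (0.79, SE 0.06), and the glucose transporter SLC2A3 (0.75, SE 0.07), with adjusted p-values from 0.00544 to 0.00875.

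Of the 29 retinoid response genes, 5 rose, 12 adjusted over the list alone, with a median of 0.25 (camera adjusted p = 9.99e-06, and adjusted p = 0.269 with an estimated correlation), and the median was 0.13 with the mean of all probe sets. They were ICAM1, an adhesion molecule (1.08, SE 0.15, adjusted p = 0.0192), AQP3 (1.04, SE 0.11, adjusted p = 0.0115), HAS3, a hyaluronan synthase (1.03, SE 0.08, adjusted p = 0.00505), DHRS9 (0.84, SE 0.16, adjusted p = 0.0420) and, named after its values were seen, HBEGF, an EGFR ligand (0.48, SE 0.06, adjusted p = 0.0157). Also chosen after their values were seen, the retinoic acid hydroxylase CYP26A1 was at 0.02 (SE 0.14, adjusted p = 0.946), at a mean of 3.70 near the limit of 3.68 for dim genes, and the receptor RARB at 0.12 (SE 0.08, adjusted p = 0.439). DHRS3, a retinal reductase likewise chosen after its values were seen, was at 1.46 with an SE of 0.40 (adjusted p = 0.0988). Of the 21 hyaluronan, aquaporin and tight junction genes, 6 rose, 10 adjusted over the list alone, with a median of 0.31 (camera adjusted p = 1.01e-05, and adjusted p = 0.269 with an estimated correlation). HAS3 and AQP3 were joined by the tight junction genes OCLN (1.14, SE 0.11, adjusted p = 0.00875) and CGN (1.12, SE 0.07, adjusted p = 0.00365).

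Of the 19 genes of the LXR and PPAR response, 8 rose and 2 fell, the counts being 8 and 2 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 1.93e-04, and adjusted p = 0.348 with an estimated correlation), and the median was 0.24 without ATRA replicate 1. ANGPTL4 was joined by CPT1A (1.16, SE 0.07, adjusted p = 0.00332) and PLIN2 (1.15, SE 0.07, adjusted p = 0.00314). ABCG1, a cholesterol exporter, fell (-1.13, SE 0.18, adjusted p = 0.0260), as did SREBF1, a transcription factor of lipid synthesis named after its values were seen (-0.40, SE 0.07, adjusted p = 0.0302). Of the 31 NRF2 response genes, 9 rose, 12 adjusted over the list alone, with a median of 0.18 (camera adjusted p = 4.12e-07, and adjusted p = 0.269 with an estimated correlation), and the median was 0.10 without the dim-gene filter. They included PIR (0.97, SE 0.08), the transporter ABCC3 (0.85, SE 0.10; others of its probe sets gave -0.01 to 0.56), GPX2 (0.83, SE 0.12) and UGDH (0.74, SE 0.10), with adjusted p-values from 0.00556 to 0.0188. Of the 39 genes of the endoplasmic reticulum stress and amino acid response, 10 rose, 16 adjusted over the list alone, with a median of 0.15 (camera adjusted p = 1.16e-07, and adjusted p = 0.348 with an estimated correlation). Examples were SDF2L1 (0.71, SE 0.08), CRELD2 (0.69, SE 0.07), the lipoprotein receptor VLDLR (0.65, SE 0.07) and SEL1L, of the degradation pathway of the endoplasmic reticulum (0.63, SE 0.08), with adjusted p-values from 0.00875 to 0.0151.

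Of the 24 basal keratinocyte and basement membrane genes, 3 fell and 1 rose, against 9 and 4 adjusted over the list alone. DST, a hemidesmosomal linker, was at -1.02 (SE 0.11, adjusted p = 0.0103), DLL1, a Notch ligand, at -0.66 (SE 0.13, adjusted p = 0.0436) and COL4A6, a basement membrane collagen, at -0.41 (SE 0.07, adjusted p = 0.0363). TNC, a matrix glycoprotein, rose by 0.64 (SE 0.09, adjusted p = 0.0176), with -0.27 from its other probe set above the limit for dim genes. The list median was -0.16 (camera adjusted p = 0.0152, and adjusted p = 0.899 with an estimated correlation), and without control replicate 1 the list no longer passed (adjusted p = 0.119, within 0.00219 to 0.899 over its alternatives).

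The remaining lists did not pass camera with ATRA. Of the 38 cytokine and chemokine genes, 5 rose and 2 fell, against 8 and 4 adjusted over the list alone. IL15 (1.05, SE 0.14), the chemokine CCL28 (0.93, SE 0.12) and IL23A, a subunit of IL-23 (0.71, SE 0.08), rose, as did LIF (0.70, SE 0.10) and CXCL16 (0.54, SE 0.10), while CXCL2 fell (-0.60, SE 0.11) beside IL24. LIF, CXCL16 and CXCL2 were named after their values were seen. The list median was -0.03 and its mean -0.01, with the test on the higher side (camera adjusted p = 0.853). Among 18 antimicrobial and alarmin genes, S100P and DEFB1 (1.45, SE 0.19) rose, 2 also adjusted over the list alone, with a median of -0.005, a mean of 0.17 and the test on the higher side (camera adjusted p = 0.578). Among 42 cornified envelope and late differentiation genes, the proteases KLK7 (1.42, SE 0.17) and KLK6 (1.11, SE 0.17) and the envelope protein SCEL (0.99, SE 0.18) rose, 3 also adjusted over the list alone, with a median of 0.07 (camera adjusted p = 0.129). The adjusted p-values of these genes lay between 0.00875 and 0.0427.

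Among 36 genes of the IL-17, IL-22 and TNF response, 3 rose: SOCS1 (0.46, SE 0.08), the NF-kappaB inhibitor NFKBIA (0.36, SE 0.07) and the airway trypsin-like protease TMPRSS11D (0.35, adjusted p = 0.0487), with a median of -0.02 (camera adjusted p = 0.798). Among 37 genes raised in psoriasis lesions, 2 rose, KLK6 and TMPRSS11D, the latter named after its values were seen, and OAS2 fell (median -0.02, camera adjusted p = 0.813). Of the 25 sterol synthesis genes, FASN fell (-0.74, SE 0.12; its other probe set gave -0.04), with a list median of -0.05 (camera adjusted p = 0.517), and of the 63 genes of cell cycle and mitosis, PCNA, the replication clamp, fell (-0.43, SE 0.08), with a median of 0.09 (camera adjusted p = 0.104). Of 37 matrix and protease genes, 6 rose and 5 fell, with LOXL2, a lysyl oxidase, at 1.63 (SE 0.21; its other probe sets gave -0.10 to 0.06), a median of 0.08, a mean of -0.02 and the test on the higher side (camera adjusted p = 0.692). FOS (0.92, SE 0.15) rose, as did EGR3 (0.66, adjusted p = 0.00875) and HBEGF, chosen after their values were seen, and MYC fell (-0.86, SE 0.13) among EGFR ligands and immediate early genes (median -0.11, camera adjusted p = 0.163). PTGES rose (0.78, SE 0.08) beside HPGD in prostaglandin metabolism (median 0.005, camera adjusted p = 0.578), and FA2H (0.51, SE 0.09) in epidermal lipid synthesis (0.08, 0.318). The adjusted p-values of the genes given here with an SE lay between 0.00903 and 0.0494. Adjusted over the list alone, 4 rose and 2 fell in the cytokine response list, 3 and 2 in the psoriasis list, 1 and 3 in the sterol list, 7 and 8 among matrix genes, 4 and 7 among immediate early genes and 2 and 3 in prostaglandin metabolism. In epidermal lipid synthesis 2 rose on that basis, and in the cell cycle list 0 passed, with 9 higher and 4 lower at an unadjusted p under 0.05.

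The heat shock genes HSPB1 (0.59, SE 0.07) and DNAJB1 (0.39, SE 0.08) rose in a list with a median of 0.008 (camera adjusted p = 0.798), and the metal transporter SLC39A8 rose (0.52, SE 0.09; others of its probe sets gave -0.37 to 0.72) in the metallothionein list (median -0.05, mean 0.002, test on the lower side, camera adjusted p = 0.798). The p53 response genes PLK2 (-0.64, SE 0.11) and XPC (-0.54, SE 0.10) fell in a list with a median of 0.04, a mean of -0.006 and the test on the lower side (camera adjusted p = 0.912). NQO1 rose (0.63, SE 0.06) in the AHR response (median -0.04, mean 0.04, test on the higher side, camera adjusted p = 0.873). The adjusted p-values of these genes lay between 0.00875 and 0.0472. Adjusted over the list alone, 2 heat shock genes rose, 2 p53 response genes fell, 1 AHR response gene rose, and 1 gene rose and 1 fell in the metallothionein list. Keratins of activated keratinocytes had a median of 0.008 and a mean of -0.13 (test on the lower side, camera adjusted p = 0.853), and 0 of 5 passed in limma, with 1 higher and 2 lower at an unadjusted p under 0.05 and adjusted over the list alone. Medians were 0.02 for the respiratory chain (camera adjusted p = 0.713) and 0.005 for ribosomal proteins (0.912), each with 0 genes past limma or at an unadjusted p under 0.05.

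Among markers of other cell types, CD14, of monocytes, rose with ATRA (0.73, SE 0.13, adjusted p = 0.0360) at a mean of 4.77, and the 12 immune markers had a median of 0.03 (camera adjusted p = 0.517). Endothelial markers had a median of 0.01 (camera adjusted p = 0.517), melanocyte markers 0.06 (0.570) and fibroblast markers 0.01, with a mean of -0.03 and the test on the lower side (0.940). Of these, 0 passed in limma, and at an unadjusted p under 0.05 there were 3 higher endothelial markers, 1 higher melanocyte marker, and 1 higher and 2 lower fibroblast markers. In the test adjusted over the list alone, 1 immune and 1 endothelial marker rose. The 67 genes named for ATRA were chosen by their values on these arrays, and for each of them both ATRA arrays lay on the same side of both control arrays. With the mean of all probe sets of a gene, 14 of them no longer passed: COL8A1 (-0.55), IL23A (0.17), SCEL (0.64), SOCS1 (0.27), NFKBIA (0.21), DST (-0.35), DLL1 (-0.18), TNC (0.16), COL4A6 (-0.26), FASN (-0.39), FA2H (0.30), GPX2 (0.30), SLC39A8 (0.22) and LOXL2 (0.31). CCL28 (0.55), ABCC3 (0.41), ANKRD37 (0.60) and OCLN (0.74) passed with that mean at smaller values than those above. Of the 14831 genes, 3283 had an unadjusted p under 0.05 and 94 changed at least 2-fold. The count of 735 ranged from 325 to 1798 over 13 other settings. It was 20 without control replicate 1, 31 without control replicate 2, 89 without ATRA replicate 1, 47 without ATRA replicate 2 and 618 without either bakusylan array. HPGD, ANGPTL4, ENO2, MX2, IFI44L, OAS2, HAS3, CPT1A, PLIN2 and TENT5A stayed past the threshold under every alternative run, and the other genes named for ATRA did not. Among these, the mean of all probe sets gave smaller values for PLIN2 (0.60), HAS3 (0.60), OAS2 (-0.80) and TENT5A (1.12).

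**Figure D2:**
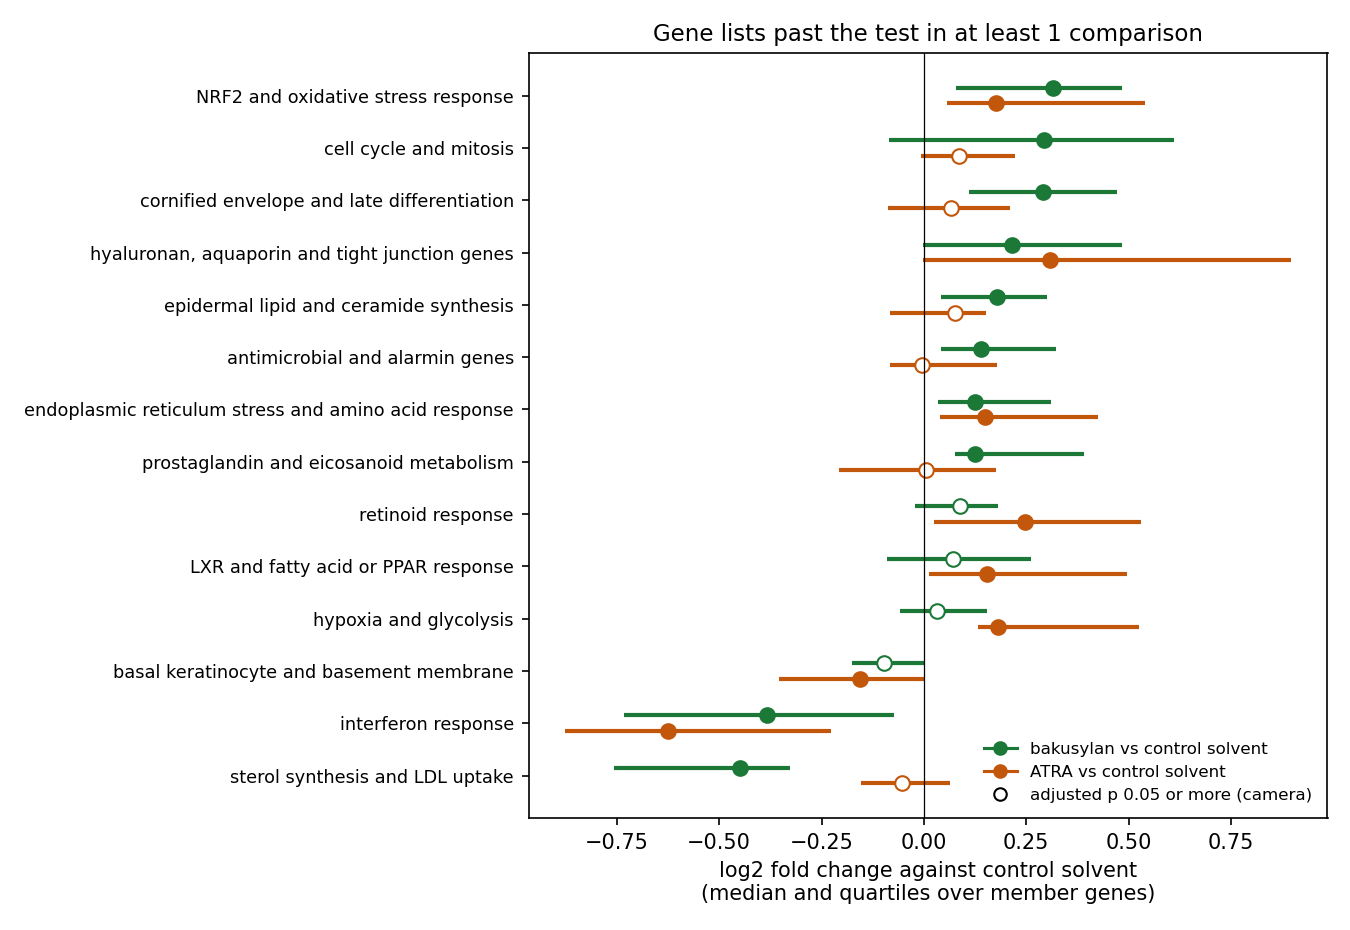
Log2 fold changes against the control solvent of the gene lists that passed camera in at least 1 comparison, for bakusylan and for ATRA; points are list medians, lines run from the lower to the upper quartile of the member genes, and open points mark a camera adjusted p of 0.05 or more. The sterol list lies at -0.45 with bakusylan and -0.05 with ATRA, and the interferon list below 0 with both.

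The direct comparison of bakusylan with ATRA asks where the ester and the retinoid differ; the doses were not matched, at 10 and 0.1 µg/ml. DTL was 5.44-fold higher with bakusylan (log2 difference 2.44, SE 0.14, n = 2 per group, adjusted p = 0.00451), at 2.34 against the control solvent with bakusylan and -0.10 with ATRA. MCM10 (1.86, SE 0.20), DKK1 (2.14, SE 0.21), IL24 (1.87, SE 0.17) and DNER (1.86, SE 0.14) were also higher with bakusylan. ENO2 was 3.60-fold lower with bakusylan (-1.85, SE 0.07, adjusted p = 0.00152), at -0.07 against the control solvent with bakusylan and 1.77 with ATRA. In all, 258 genes differed, 138 of them higher with bakusylan (53.5%) and 120 lower. That split has no firm direction: it turned to 28 higher and 41 lower with the replicate number as a block, 74 and 79 with every probe set tested, 27 and 32 with only the 4 arrays compared or without either control array, and 1 and 2 without ATRA replicate 1.

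GALNT12 (-2.11, SE 0.35), ANGPTL4 (-1.47, SE 0.08), LOXL2 (-1.42, SE 0.21) and CIDEA, a lipid droplet protein (-1.43, SE 0.18), were lower with bakusylan, with adjusted p-values of the named genes at or under 0.0489. Of the 25 sterol synthesis genes, 13 were lower with bakusylan, 21 adjusted over the list alone, with a median difference of -0.45 (camera adjusted p = 1.88e-20, and adjusted p = 0.267 with an estimated correlation). INSIG1 differed by -1.28 (SE 0.07) and HMGCS1 by -1.02 (SE 0.06), each at an adjusted p = 0.00451. Of the 36 genes of hypoxia and glycolysis, 9 were lower with bakusylan, with a median of -0.25 (camera adjusted p = 5.14e-14, and adjusted p = 0.533 with an estimated correlation). There were 21 lower and 1 higher adjusted over the list alone. Of the 19 genes of the LXR and PPAR response, 4 were lower, 6 adjusted over the list alone, with a median of -0.13 (camera adjusted p = 3.06e-05, and adjusted p = 0.533 with an estimated correlation). These were ANGPTL4, CPT1A (-0.72, SE 0.07), PLIN2 (-0.44, SE 0.07) and, named after its values were seen, ACADVL, a fatty acid dehydrogenase (-0.50, SE 0.06).

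Of the 29 retinoid response genes, 3 were lower with bakusylan: ICAM1 (-1.41, SE 0.15, adjusted p = 0.0201), HAS3 (-0.99, SE 0.08, adjusted p = 0.00829) and HBEGF (-0.39, SE 0.06, adjusted p = 0.0437), named after its values were seen. The counts were 4 lower and 1 higher adjusted over the list alone, with a median of -0.16 (camera adjusted p = 0.00177, and adjusted p = 0.533 with an estimated correlation), and the median was -0.09 without bakusylan replicate 1. AQP3, which rose with each compound, differed by -0.20 (95% CI -0.48 to 0.08, adjusted p = 0.439). Of the 45 interferon response genes, 2 were higher with bakusylan, MX2 (0.68, SE 0.10, adjusted p = 0.0363) and OAS2 (0.53, SE 0.07, adjusted p = 0.0289). There were 14 higher and 1 lower adjusted over the list alone, with a median of 0.14 (camera adjusted p = 2.3e-04, and adjusted p = 0.722 with an estimated correlation), and the median was 0.06 without ATRA replicate 2. IFIT1 differed by 0.36 (95% CI -0.34 to 1.06, adjusted p = 0.597).

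Of the 63 genes of cell cycle and mitosis, 15 were higher with bakusylan and 2 lower, against 24 and 11 adjusted over the list alone. CCNE2 differed by 1.69 (SE 0.06, adjusted p = 0.00128) and PCNA by 1.07 (SE 0.08, adjusted p = 0.00829). The lower genes were the mitotic genes KIF20A (-0.88, SE 0.12, adjusted p = 0.0330) and DLGAP5 (-0.79, SE 0.13, adjusted p = 0.0467), named after their values were seen. The list median was 0.11 (camera adjusted p = 0.0126, and adjusted p = 0.750 with an estimated correlation), and the median was 0.18 without bakusylan replicate 1, and the list no longer passed without bakusylan replicate 2 (adjusted p = 0.0847, within 0.00127 to 0.750 over its alternatives). Of the 42 cornified envelope genes, 0 differed in limma, also adjusted over the list alone, with 11 higher and 3 lower at an unadjusted p under 0.05, and the median was 0.13 (camera adjusted p = 0.0121, and adjusted p = 0.750 with an estimated correlation). That list no longer passed without bakusylan replicate 1 (median 0.08, adjusted p = 0.0778) or ATRA replicate 2 (adjusted p = 0.121), within 1.77e-04 to 0.750 over its alternatives, and its median was 0.08 without the dim-gene filter.

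For the NRF2 response, whose list passed camera with each compound at the preset correlation, 0 of 31 genes differed between the compounds in limma, with 6 higher and 4 lower at an unadjusted p under 0.05, 2 higher and 2 lower adjusted over the list alone, and a median of 0.06 (camera adjusted p = 0.253). The difference between bakusylan and ATRA was 0.12 for PIR (95% CI -0.07 to 0.31), 0.06 for NQO1 (95% CI -0.09 to 0.20) and 0.06 for GPX2 (95% CI -0.22 to 0.34). The endoplasmic reticulum list (median -0.04, camera adjusted p = 0.117) and the hyaluronan, aquaporin and tight junction list (median -0.11, camera adjusted p = 0.102) did not pass either. Of the 14831 genes, 2534 had an unadjusted p under 0.05 and 42 differed at least 2-fold. For each of the 10 genes named for the direct comparison, chosen by their values on these arrays, both bakusylan arrays lay on the same side of both ATRA arrays. LOXL2 no longer passed with the mean of its probe sets (-0.38), and MCM10 was at 0.92 with every probe set tested on its own. The count of 258 ranged from 59 to 1014 over 13 other settings, and was 5 without bakusylan replicate 1, 3 without ATRA replicate 1, 11 without ATRA replicate 2, 218 without bakusylan replicate 2 and 59 without either control array. ENO2 stayed past the threshold under every alternative run, and the other genes named for this comparison did not.

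Both compounds also changed genes in common. Of the 221 genes that changed with bakusylan, 90 (40.7%) changed in the same direction with ATRA, 59 higher and 31 lower, and 3 changed in opposite directions. HPGD, AQP3, CGN, PTGES, PIR, GPX2, NQO1, SDF2L1 and CRELD2 were among those that rose with each, and IFIT1, IFIT3, MX2, IFI44L, OAS2 and FASN among those that fell. Independent changes would give 4.27 higher and 1.44 lower genes in common, a number that leaves the shared control arrays out of account. The covariance of the log2 fold changes was 0.0256 against 0.00491 in the simulations, and Pearson's r across genes, which are not independent replicates, was 0.559 against 0.500. With a separate control array for each compound the covariance was 0.0183 or 0.0199, depending on the control array given to each. Of the 90 genes, 13 differed between the compounds in the direct test, among them HPGD (-0.96, SE 0.13, adjusted p = 0.0306). The overlap was 44 without the dim-gene filter and 30 with the replicate number as a block. It fell to 2 without either control array, to 17 without bakusylan replicate 1, 1 without bakusylan replicate 2, 18 without ATRA replicate 1 and 10 without ATRA replicate 2.

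**Figure D3:**
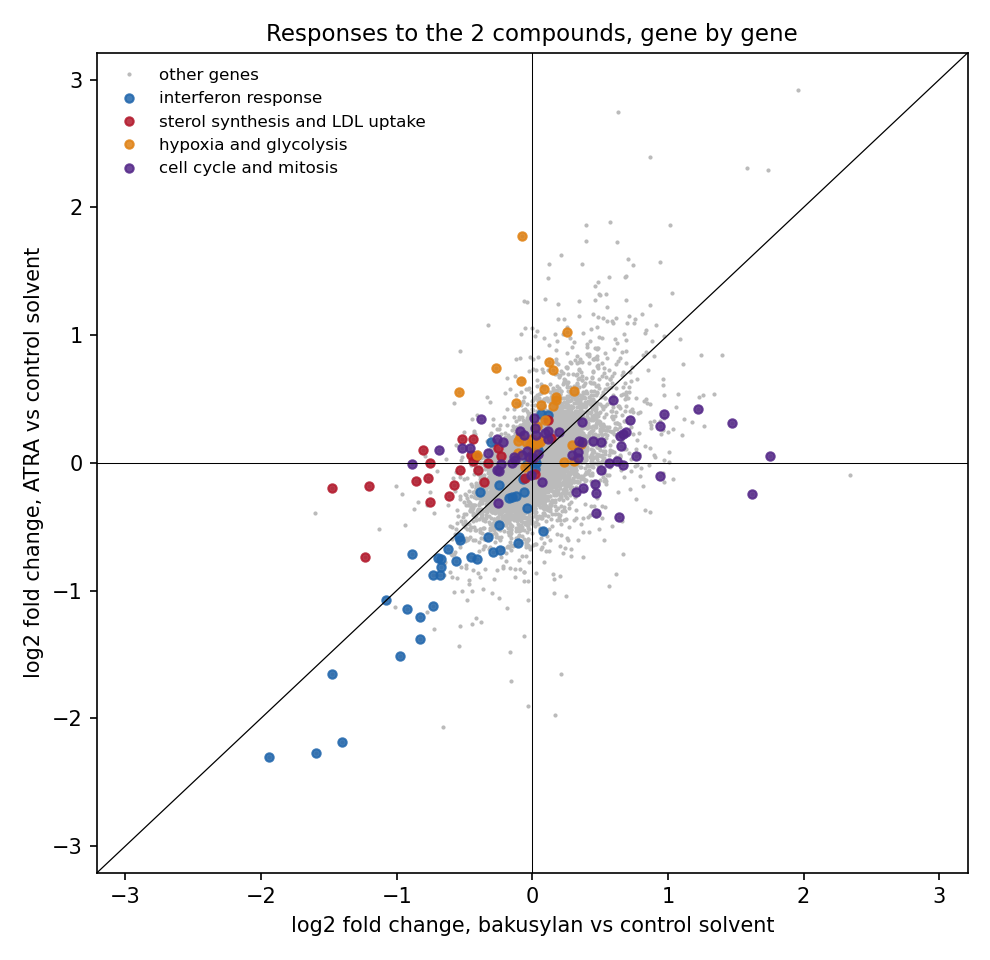
Log2 fold change with ATRA against that with bakusylan, each relative to the control solvent, for the genes tested except XIST and Y-linked genes, with the genes of 4 lists in colour and a line where both changes are equal. Of the 25 sterol synthesis genes 22 lie below 0 for bakusylan, with INSIG1 at -1.48 against -0.19 for ATRA, and of the 45 interferon response genes 37 lie below 0 for bakusylan and 39 for ATRA.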

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

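The test of the interferon genes between the compounds, that of intensity bias for the sterol genes and all tests of the replication genes were chosen only after the result was seen. Outside the comparisons, 6075 probe sets that do not have exactly 1 gene symbol, those with several symbols included, were tested. Of these, 1 changed: it was lower with ATRA than with the control solvent.

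Interferon response genes were lower with both compounds than with the control solvent at the preset correlation (adjusted p = 0.220 for bakusylan and 0.269 for ATRA with an estimated correlation). A single high control array is argued against: with either control array alone as the baseline, the list median was -0.37 or lower for both compounds, below the central 95% of 10000 random lists matched on expression. That both control cultures were high in these genes for another reason than treatment cannot be told apart from an effect of both compounds, since there are 2 control arrays, which differed over the list by a median of 0.14 (log2), and no arrays without cytokines. For the part that separates the compounds, such controls would leave no difference. The list was higher with bakusylan than with ATRA by a median of 0.14, and by 0.06 without ATRA replicate 2. The median of 0.14 lay above matched random lists (-0.03 to 0.05). Those lists draw genes independently, so they do not show how far genes that move together shift between arrays of 1 treatment. The median absolute difference between the control arrays was also 0.14 over this list. That part may be an effect of treatment or of spread between arrays. Its list test rests on the preset correlation (camera adjusted p = 0.722 with an estimated correlation).

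Sterol synthesis and LDL uptake genes were lower with bakusylan. An intensity-dependent bias between arrays is argued against by the list median of -0.45, below that of each of 10000 random lists matched on expression. A single deviating array is argued against as well, since over the 4 pairs of a bakusylan and a control array the median closest to 0 was -0.45. An effect of bakusylan on this pathway may account for the pattern, as a hypothesis found and tested on the same arrays. The list test did not pass with an estimated correlation (camera adjusted p = 0.129). That alternative also falls to 3 residual degrees of freedom, and 0 lists passed it in any comparison, so it does not show that correlation between genes undoes the shift.

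Replication genes, 22 members of a cell cycle list that did not pass with an estimated correlation (adjusted p = 0.498), were higher with bakusylan, with 13 past the threshold. Their median of 0.63 lay above that of each of 10000 random lists matched on expression. This cannot decide on an intensity-dependent bias, since the 22 genes were singled out after their values were seen. A single deviating array is argued against by the smallest median over the 4 array pairs, 0.54, though for these same genes. A larger share of cycling cells would raise mitosis genes too, but the 38 mitosis genes had a median of -0.03, with 18 at positive values. The difference of the medians was 0.66 (permutation p = 1e-05, the smallest that 100000 permutations can give, with genes taken as independent). Because the split was made after the members' values were seen, this p describes it and is no independent evidence against such a share. An intensity-dependent bias, a larger share of cycling cells, a larger share of cells in S phase and a change in the replication genes themselves all remain possible. None of these was tested apart from the others.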

How the results depend on the processing

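All alternatives were planned. Among the named genes and the lists that passed camera (10, 8 and 7), none reversed its direction under the alternatives run for it. With every probe set tested, however, only the probe set of a gene with the smallest p was followed. Of the genes named for bakusylan 4, and of those named for ATRA 5, had at least 1 other probe set of opposite sign. Lists were not run with array weights, centred arrays, every probe set, the 50% filter, the robust trend or only the 4 arrays, and lists that did not pass were not followed. The split into higher and lower genes turned in the direct comparison (28 and 41 with the block, 74 and 79 with every probe set, 27 and 32 with only the 4 arrays or without either control array, 1 and 2 without ATRA replicate 1) and for ATRA (649 and 677 with the dimmest 50% of genes left out). In all settings the median of all genes stayed within 0.024 (log2) of 0. The counts of changed genes kept within 1.5 times their value with the mean of all probe sets, a second quantile normalization and arrays centred on their median. The counts for bakusylan, ATRA and the direct comparison are given in that order where 3 stand together. They were 490, 1326 and 651 with the dimmest 50% of genes left out, 865, 1735 and 996 with an intensity trend, 903, 1798 and 1014 with a robust trend, 68, 474 and 69 with the replicate number as a block, 536, 1567 and 748 at an adjusted p under 0.10, and 141, 325 and 158 with a fold change of at least 1.5 required. For bakusylan and the direct comparison they were 120 and 163 without the filter, 138 and 153 with every probe set tested, and 61 and 59 with only the 4 arrays compared. For bakusylan the count was 104 with array weights. Leaving out 1 array gave 6 to 61, 20 to 618 and 3 to 218 genes. The cause of these moves was not tested, except that fewer arrays leave fewer degrees of freedom and that a lone array is assumed to vary like the other groups. The labels do not say whether the replicate numbers pair the samples. Correlations of the deviations between groups were -0.07, 0.004 and -0.009 across genes. These show no large shared replicate effect, but cannot tell whether the samples were paired. The overlap of the compounds was 44 without the filter, 30 with the block and 1 to 18 without 1 array, and their covariance was 0.0197 to 0.0353 without 1 array. With an estimated correlation 0 lists passed camera in each comparison, and 4, 4 and 2 had an unadjusted p under 0.05. For the NRF2 list a larger correlation between genes is argued against as the reason, since its estimate was 0.009, under the preset 0.01. Its unadjusted camera p still went from 1.46e-12 to 0.0056 with bakusylan and from 5.49e-08 to 0.0118 with ATRA. The alternative also takes its p from the 3 residual degrees of freedom, whereas the preset test takes as many as the genes allow. For this list, whose correlation was not larger, the loss of degrees of freedom is what raised p. For the other lists the 2 changes were not run apart. At the preset correlation 10, 8 and 7 lists passed. Without any 1 array, 7, 7 and 5 of these lists kept their call. Of the 51, 67 and 10 genes named, 8, 10 and 1 kept their side of the threshold without any 1 array, and 5, 10 and 1 under all alternatives. Keeping a side includes staying short of the threshold: 5 of the 51 genes named for bakusylan had not passed. These, DEFB1, DHRS9, DSC2, KLK12 and PGLYRP2, are all among the 8, and KLK12 and PGLYRP2 are among the 5 kept under all alternatives. Signal over background limits the dimmest genes: those below a log2 value of 3.68 were not tested, and calls near it rest on weak signal.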

Other observations

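The chaperone tests were chosen only after the result was seen, and those of fatty acid oxidation genes before it, though after the values of related genes such as CPT1A. Besides the lists fixed at the start, 3 groupings were tried in all: replication against mitosis genes, fatty acid oxidation, and chaperones against amino acid genes.

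A list of genes of mitochondrial and peroxisomal fatty acid oxidation was written without the genes already seen, such as CPT1A. Of its 25 genes tested, 3 rose with ATRA: CPT2, a carnitine acyltransferase (log2 change 0.68, SE 0.06, adjusted p = 0.00875), ETFDH, an electron transfer dehydrogenase (0.42, adjusted p = 0.0281), and ECI2, an isomerase of this pathway (0.31, adjusted p = 0.0486). With ATRA 18 genes were at positive values, with a median of 0.11 (camera adjusted p = 0.006 over the 2 comparisons, and adjusted p = 0.334 with an estimated correlation). With bakusylan 0 genes passed in limma, 5 were higher at an unadjusted p under 0.05, 17 were at positive values and the median was 0.06 (camera adjusted p = 0.04, and adjusted p = 0.334 with an estimated correlation). At the preset correlation alone, the ATRA result is consistent with a rise of this pathway, while with bakusylan the list shifted without any gene past the threshold.

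Within the endoplasmic reticulum list, the 15 chaperone and folding genes had a median of 0.35 with ATRA, with 7 that rose, and the 24 genes of the amino acid response 0.13, with 3 that rose (permutation p = 0.013 for the difference, with genes taken as independent). With bakusylan the medians were 0.30 and 0.06 (permutation p = 0.0025). Because the split was made after the members' values were seen, these p-values describe it and are no independent evidence of a difference. The whole list did not pass with an estimated correlation (adjusted p = 0.348 with ATRA and 0.498 with bakusylan).

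The bakusylan arrays differed in their similarity to the ATRA arrays. Over the 14831 genes tested, the correlation with the ATRA arrays was 0.994 for bakusylan replicate 1 and 0.996 for replicate 2. With the control arrays it was 0.9953 and 0.9962 for replicate 1, and 0.9951 and 0.9955 for replicate 2. Replicate 2 was thus closer to the ATRA arrays (0.9959 and 0.9960) than to the control arrays, while replicate 1 was closer to the control arrays. The covariance of the fold changes of the compounds was 0.0315 without bakusylan replicate 1 and 0.0197 without replicate 2, against 0.0256 with all arrays.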
